A study of Homo sapiens with 36 samples.

How the data were processed

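RNA of Caco-2 cells exposed to MNNG, MNU, NDEA, NDMA, NPIP or NPYR for 1, 6 or 24 h was measured on 36 Agilent dual-channel arrays, 2 biological replicates for each of 18 groups. On every array, treated and vehicle RNA carried different dyes: in replicate 1 of each group the treated RNA was in Cy5, and in replicate 2 in Cy3. The deposited values are log ratios of both channels, read here as log2: 4 decimals, both signs and values beyond what log10 ratios of array signals can reach exclude log10, but natural logarithms are not excluded. Sizes depend on that base and are given as log2 values without folds; the tests do not depend on it. The authors had turned the log ratios to one direction before they were deposited, since replicates of opposite dye correlated positively across genes. That this direction is treated over vehicle is not stated in the sources used here: it was taken because metallothioneins and stress genes such as ATF3 are then higher in treated cells, and the other reading would turn every sign. Background correction, normalization and the rule that left features without a value are not given in the sources used here. The array medians were close to 0 as deposited, the furthest at -0.037.

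Between 31436 and 36815 of the 45220 features had a value per array. The number of arrays limits the precision; signal intensities were not used here. Features were paired with gene symbols from the platform's annotation, 31332 with 1 gene, and 31291 of the symbols matched a gene of the reference annotation used for names. A gene's value was the mean of its features that had a value on at least 30 of the 36 arrays, after each array was centred on its median, which left 13283 genes. Of these, 11249 had a value on every array. Another 6312 features without a gene name passed the same minimum, were tested apart and are counted in the closing section.

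Samples were grouped by compound and time as labelled. One limma fit (limma 3.58.1 in R 4.3.3) over all arrays had a coefficient for each of the 18 groups and a term for dye orientation, which in this design is the same as the replicate number as a block. Residual degrees of freedom were 17, and the empirical Bayes prior added 2.95. Each coefficient was tested against 0 with limma, as were the contrasts between classes, between related compounds and between times, with an F test for any difference between the 3 times of a compound. All tests are 2-sided, with Benjamini-Hochberg adjustment over genes within each comparison and a threshold of 0.05. A gene is called when it passes that threshold. The groups, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, except where stated. Intervals of differences are 95% intervals from the same fit.

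Camera, limma's competitive test of a gene set, was run on the genes with a value on every array for the 33 of 34 lists with at least 5 such members, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over 594 tests. Beside it stand the numbers of list members past the threshold over all genes and adjusted over the list alone. The lists cover DNA repair, cell cycle, stress responses, signalling, metabolism of foreign compounds, core metabolism, ribosomes and markers of intestinal and other cell types. Some genes stand in several lists, so calls of different lists are not independent.

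Genes were named by a rule: per compound and time the 5 largest rises and 5 largest falls among called genes with the same direction on both arrays, per called list the 4 members with the smallest p, per class or compound contrast the 3 largest each way, and a short list of stress, repair and cytochrome genes open to naming whatever their values. Some genes that meet the rule were left out for length. Agreement between compounds was measured by correlation across genes and by the overlap of called genes against the number that independent draws give. Slopes between replicates are major axis slopes after the dye term was removed.

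The alternatives were no replicate block, no centring, arrays scaled to one spread, array weights, the most variable probe of a gene, genes with a value on every array, a robust prior, and each array left out in turn. Added after seeing the data were fits of each time alone, without the MNNG 6 h arrays, without the 3 replicate 1 arrays of NDEA, NPIP and NPYR at 24 h, a count of genes with the same direction on both arrays, and gene lists with each array left out. The fit was tested on simulated data. Its noise had each gene's spread pooled over all arrays, the same in every group, so it does not show how the fit does where groups differ in spread. Of changes of 0.5, 1 and 2 (log2) planted in NPIP at 6 h over 13271 genes, 13.4%, 82.1% and 100% were recovered, with 7 unchanged genes called. For changes planted in MNU at 1 h over 13266 genes the shares were 32.8%, 83.6% and 98.5%, with 8 unchanged genes called. In 16 simulated groups without change the highest count was 0. Features with several genes were left out, 93 in all.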

Results

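RNA of Caco-2 cells, a human colon adenocarcinoma line with features of enterocytes, was measured after exposure to 1 of 6 N-nitroso compounds for 1, 6 or 24 h. MNNG (1 µM) and MNU (1 mM) are nitrosamides, which alkylate DNA without enzymes. NDEA (50 mM) and NDMA (100 mM) are dialkyl nitrosamines, and NPIP (40 mM) and NPYR (100 mM) are cyclic nitrosamines, classes that need activation by cytochrome P450 enzymes. Each of the 18 combinations of compound and time had 2 biological replicates, and each of the 36 Agilent arrays compared treated with vehicle RNA, with the dyes swapped between replicates. Between 31436 and 36815 of the 45220 features had a value per array, and 13283 genes were tested. Signal intensities were not used here, and the number of arrays limits the precision. Log2 ratios are given as treated over vehicle with 2 arrays in every group; the log base and the sign convention are not stated in the sources, and the basis for both is given with the processing. With the dye term removed, the replicates correlated across genes, which are not independent replicates, at 0.713 to 0.884 in the nitrosamine groups at 6 and 24 h, at 0.293 to 0.399 in these groups at 1 h and at 0.0985 to 0.311 in the nitrosamide groups. As deposited the same correlations were 0.642 to 0.855, 0.207 to 0.308 and 0.0135 to 0.18.

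The first question was which genes each compound changed against its vehicle. At 1 h the immediate early genes, which growth factor and stress signals switch on within minutes, rose with the nitrosamides and fell with the nitrosamines. MNU raised 12 of 25 measured members, including JUN, a subunit of the AP-1 transcription factor, at 1.49 ± 0.13 (SE, adjusted p = 2.45e-06), and ATF3, a stress-induced transcription factor, at 1.73 ± 0.26 (SE, adjusted p = 0.00163). MNNG raised 2, JUN at 0.88 ± 0.13 (SE, adjusted p = 0.0061) and the zinc finger factor KLF6 at 0.78 ± 0.11 (SE, adjusted p = 0.0061). NDEA, NDMA, NPIP and NPYR lowered 15, 18, 14 and 14 members. IER3, an early response gene, fell to -2.59, -2.73, -2.48 and -2.67 with these 4 compounds (SE 0.13; largest adjusted p = 4.47e-10). FOS, the partner of JUN in AP-1, fell to -3.18 with NDMA and to -1.66 with NPYR. JUN itself went both ways, with 0.79 ± 0.13 for NDEA, 0.94 ± 0.13 for NPIP and -1.13 ± 0.13 for NDMA (largest adjusted p = 0.000768). Leaving out 1 array ended the calls of ATF3 with MNU (1.088 without replicate 1) and of JUN with NDEA (0.6822 without replicate 2). It also ended those of JUN and KLF6 with MNNG (0.6823 to 0.9222 without either replicate). Adjusted over the list alone, 18 members rose with MNU and 12 with MNNG, and 18, 20, 17 and 20 fell with the nitrosamines. The camera test of the list passed for all 6 compounds, with adjusted p from 8.8e-62 to 5.7e-21, and from 1.58e-05 to 0.00167 with an estimated correlation.

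Other signalling genes moved alongside at 1 h. The TGF-beta, p53 and Wnt lists below share CCN2, BTG2 and MYC, in that order, with the immediate early list. Their calls are thus not independent of that list. EDN1, the endothelin precursor, fell to -3.16, -2.85, -2.75 and -2.80 with NDEA, NDMA, NPIP and NPYR (SE 0.21), and MIR17HG, the host transcript of a microRNA cluster, to -2.84, -2.21, -3.35 and -3.99 (SE 0.18). GDF15, a stress-induced cytokine, was 1.28 ± 0.15 with MNU and -3.18 ± 0.15 with NDMA. Of 21 NF-kB and inflammation genes, 5, 5, 4 and 4 fell with NDEA, NDMA, NPIP and NPYR (7, 5, 6 and 5 adjusted over the list alone), and 3 rose with MNU (6 adjusted over the list alone). The chemokine CXCL1 fell to -2.92 with NDMA (adjusted p = 1.69e-07) and CXCL3 was 1.05 ± 0.21 (SE, adjusted p = 0.0301) with MNU. The list passed camera for these 5 compounds, and with an estimated correlation for all but NPYR (adjusted p = 0.0856 with an estimated correlation, and 0.0888 without replicate 1). Of 11 TGF-beta and BMP targets, 5 fell with NDMA, ID2 to -1.48 (5 adjusted over the list alone, camera adjusted p = 4.71e-09), and ID2 was 0.65 ± 0.13 with MNU. The TGF-beta list was also called lower with NDEA, NPIP and NPYR, 4, 3 and 3 members (4, 4 and 5 adjusted over the list alone; adjusted p = 0.0599, 0.128 and 0.0857 with an estimated correlation, and 0.138 for NPIP without replicate 1). It was called higher with MNU, 1 member (5 adjusted over the list alone, camera adjusted p = 3.21e-07), and with MNNG, 0 members (adjusted p = 0.247 with an estimated correlation, and 0.358 without replicate 1). Of 24 p53 targets, 3 rose with MNU (5 adjusted over the list alone, camera adjusted p = 1.25e-06), PMAIP1, a mediator of apoptosis, PLK3 and GADD45A at 0.88, 0.82 and 0.69. The p53 list was called lower with NDMA and NPIP at 1 h, 3 members each (4 each adjusted over the list alone; adjusted p = 0.0615 and 0.131 with an estimated correlation, and 0.183 for NPIP without replicate 1), and with NDEA, where 3 members fell, it was not called (camera adjusted p = 0.205). Omission of 1 array ended the calls of these MNU genes, CXCL3, ID2, PLK3 and GADD45A without either replicate (adjusted p = 0.163 to 0.764), GDF15 without replicate 1 (0.0778) and PMAIP1 without replicate 2 (0.133). Replication-dependent histone genes rose with NDEA and NPIP at 1 h, 4 and 6 of 24 (9 and 8 adjusted over the list alone, camera adjusted p of 5.26e-09 and 6.16e-11). The histone list was called lower at 1 h with MNNG and MNU, though no member passed over all genes (0 and 1 adjusted over the list alone, camera adjusted p of 4.79e-06 and 4.79e-08), and higher with NDMA and NPYR, 0 and 2 of 24 (5 and 4 adjusted over the list alone; adjusted p = 0.172 and 0.105 with an estimated correlation, and 0.448 for NDMA without replicate 2). Wnt targets and stem cell markers fell with NDEA, NDMA, NPIP and NPYR, 3, 3, 3 and 3 of 12 (4, 3, 3 and 3 adjusted over the list alone, camera adjusted p of 2.35e-05, 9.93e-05, 0.0477 and 0.000253). The NPIP call of that list was lost with an estimated correlation (adjusted p = 0.255 with an estimated correlation, and 0.159 without replicate 1). Among the risers, IQCN reached 2.84 ± 0.21 (SE, adjusted p = 5.56e-08) with NDEA and 2.16 ± 0.21 (SE, adjusted p = 4.25e-06) with NPIP.

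At 1 h, 44 genes rose and 3 fell with MNU, against 93 and 177 with NDEA, 25 and 171 with NDMA, 59 and 165 with NPIP, and 47 and 164 with NPYR. With MNNG 3 genes rose, JUN and KLF6 among them. The 4 nitrosamines shared 72 genes that fell, where independent draws, which leave out any shared vehicle RNA, give 0.000353. Without replicate 1 or without replicate 2 the counts were 11 and 18 for MNU, 88 and 120 for NDEA, 119 and 90 for NDMA, 77 and 65 for NPIP, 70 and 65 for NPYR and 17 and 5 for MNNG. With arrays scaled to one spread they were 643 (408 higher), 1425 (706 higher), 795 (278 higher), 1179 (507 higher), 1179 (494 higher) and 425 (217 higher) in the same order.

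**Figure D1:**
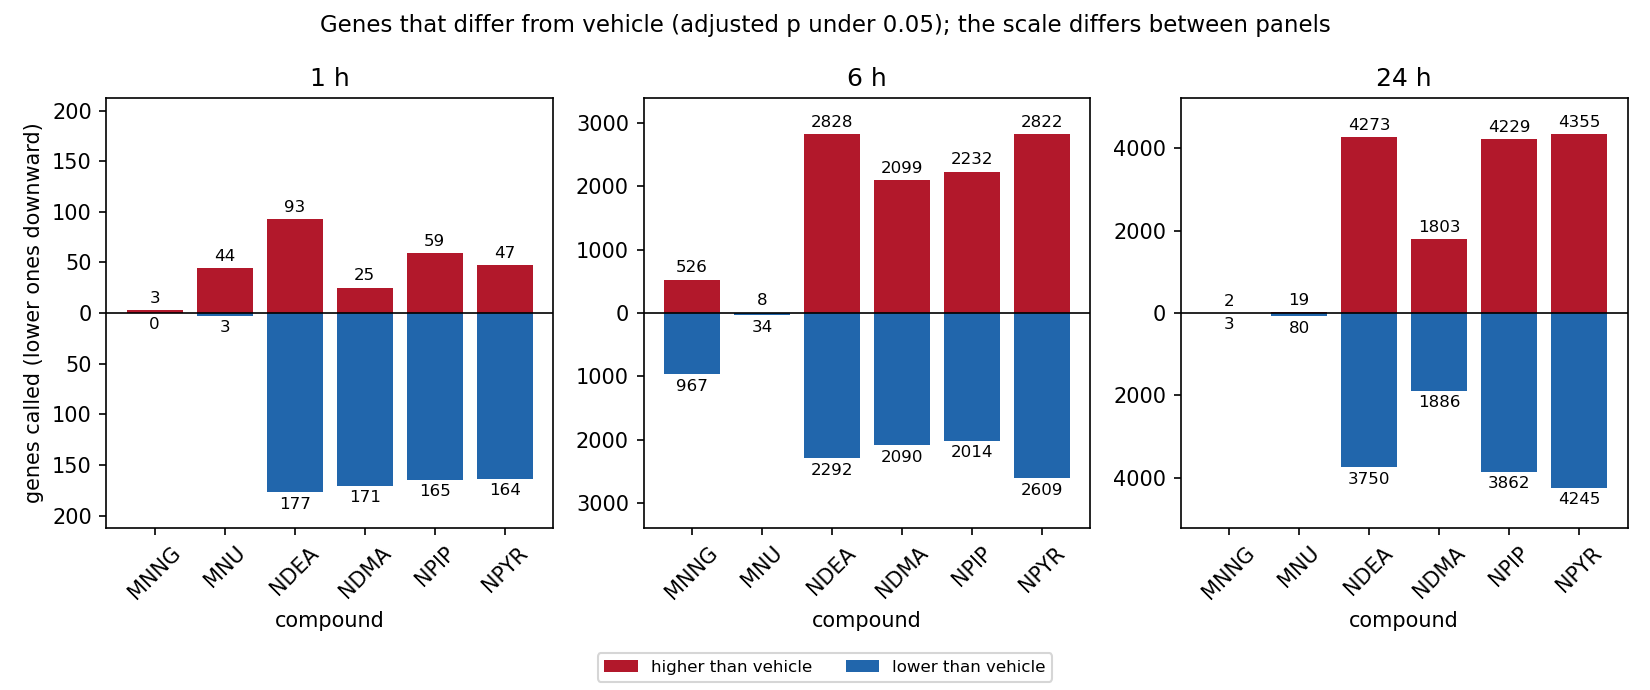
Number of genes called higher (red, upward) and lower (blue, downward) than vehicle for each compound, in a panel per time with its own scale. At 24 h NDMA has 3689 called genes and the 3 other nitrosamines between 8023 and 8600.

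At 6 h all 4 nitrosamines raised metallothioneins, small proteins that bind zinc and other metals, and lowered DUSP6, MYC and SLC2A1. The direction of the metallothioneins is no finding of its own, since the sign convention was taken so that these genes and ATF3 are higher in treated cells. All 8 measured members of the metallothionein list rose with each of the 4 (8 each adjusted over the list alone), with medians of 3.08, 2.50, 4.84 and 3.11 for NDEA, NDMA, NPIP and NPYR. That list also holds the zinc exporter SLC30A1, which is not a metallothionein. MT1E reached 6.09 ± 0.30 (SE, adjusted p = 2.05e-11) with NPIP and 3.35 ± 0.30 (SE, adjusted p = 8.18e-08) with NDMA, and MT2A 4.31 ± 0.23 (SE, adjusted p = 1.22e-10) with NPYR. Too few members had a value on every array for camera, and probes of the near-identical metallothionein genes can share signal. ARRDC3, an arrestin-domain protein, rose with all 4, from 2.99 ± 0.32 with NDMA to 5.43 ± 0.32 with NPYR. DUSP6, a phosphatase that inactivates ERK kinases, fell to -4.49, -3.73, -2.68 and -4.59 (SE 0.15), and the growth regulator MYC to -3.54, -3.21, -1.75 and -3.44 (SE 0.17). ANKRD1, a transcriptional cofactor, and TNS4, a focal adhesion protein, fell to -4.43 and -3.85 with NDEA. SLC2A1, the glucose transporter, fell to -3.24, -3.03, -2.62 and -3.10 (SE 0.098; largest adjusted p = 9.12e-14). CYP1A1, a target of the aryl hydrocarbon receptor, rose with NDMA to 1.88 ± 0.19 (SE, adjusted p = 2.65e-07) and fell with NDEA (-1.89 ± 0.19), NPIP (-2.02 ± 0.19) and NPYR (-0.92 ± 0.19). MAT2A, which makes S-adenosylmethionine, fell to -3.89 with NPIP.

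The ATF4 list, genes of the integrated stress response to amino acid shortage and other stresses, rose with each nitrosamine at 6 h. With NDEA, NDMA, NPIP and NPYR, 20, 17, 19 and 19 of 26 members rose (20, 17, 20 and 19 adjusted over the list alone), while 1, 2, 1 and 3 fell. ASNS, asparagine synthetase, reached 2.11 ± 0.12 (SE, adjusted p = 8.27e-11) with NDEA, and DDIT4, an inhibitor of mTORC1, 3.36 ± 0.13 (SE, adjusted p = 1.3e-13) with NPIP. The camera adjusted p ran from 6.16e-11 to 5.49e-07, and from 0.000672 to 0.0039 with an estimated correlation. Replication-dependent histone genes rose with NDEA (22 of 24), NPIP (23) and NPYR (22), or 22, 24 and 23 adjusted over the list alone, with camera adjusted p of 1.64e-13, 2e-23 and 1.05e-08. H3C4 reached 3.02 ± 0.12 (SE, adjusted p = 2.45e-13) with NPIP. With NDMA 10 histone genes rose (11 adjusted over the list alone; adjusted p = 0.352 with an estimated correlation, and 0.179 without replicate 1). The G1/S and DNA replication list moved the other way, with 16, 14, 17 and 20 of 28 members lower (18, 15, 18 and 20 adjusted over the list alone), CCNE1, cyclin E, to -0.95 with NDEA. The NDMA call of that list was lost with an estimated correlation (adjusted p = 0.105 with an estimated correlation). Ribosome biogenesis genes fell in all 4, 18, 18, 15 and 15 of 22 (19, 19, 16 and 15 adjusted over the list alone), with NOP16 at -1.73 ± 0.082 for NDEA and camera adjusted p up to 7.4e-06.

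Mitotic genes rose with NDMA (19 of 30, NEK2 at 1.19 ± 0.10) and NPYR (19, NDC80, a kinetochore protein, at 1.54 ± 0.13), or 19 and 20 adjusted over the list alone, with camera adjusted p of 1.9e-06 and 7.97e-07. With NPIP 15 rose (16 adjusted over the list alone; adjusted p = 0.22 with an estimated correlation). NF-kB and inflammation genes rose with NPIP, 13 of 21 with 3 lower (13 and 3 adjusted over the list alone, camera adjusted p = 0.00209), NFKBIA, the NF-kB inhibitor, at 2.01 ± 0.12. Wnt targets and stem cell markers fell with NDEA (9 of 12; 10 adjusted over the list alone; camera adjusted p = 0.000347), among them CCND1, cyclin D1, to -1.98. The Wnt list was called lower with NDMA, NPIP and NPYR at 6 h too, 5, 6 and 8 members (5, 6 and 8 adjusted over the list alone; adjusted p = 0.0846, 0.105 and 0.0558 with an estimated correlation). With NDMA the NF-kB list was called lower, 10 members (11 adjusted over the list alone; adjusted p = 0.112 with an estimated correlation, and 0.0855 without replicate 2). In total 2828 genes rose and 2292 fell with NDEA, 2099 and 2090 with NDMA, 2232 and 2014 with NPIP, and 2822 and 2609 with NPYR. All 4 shared 979 risers and 986 fallers, against 16 and 10.8 from independent draws of the same kind. Without replicate 1 or without replicate 2 the counts were 2830 and 3436 for NDEA, 2241 and 2234 for NDMA, 2223 and 2117 for NPIP, and 4047 and 2895 for NPYR.

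**Figure D2:**
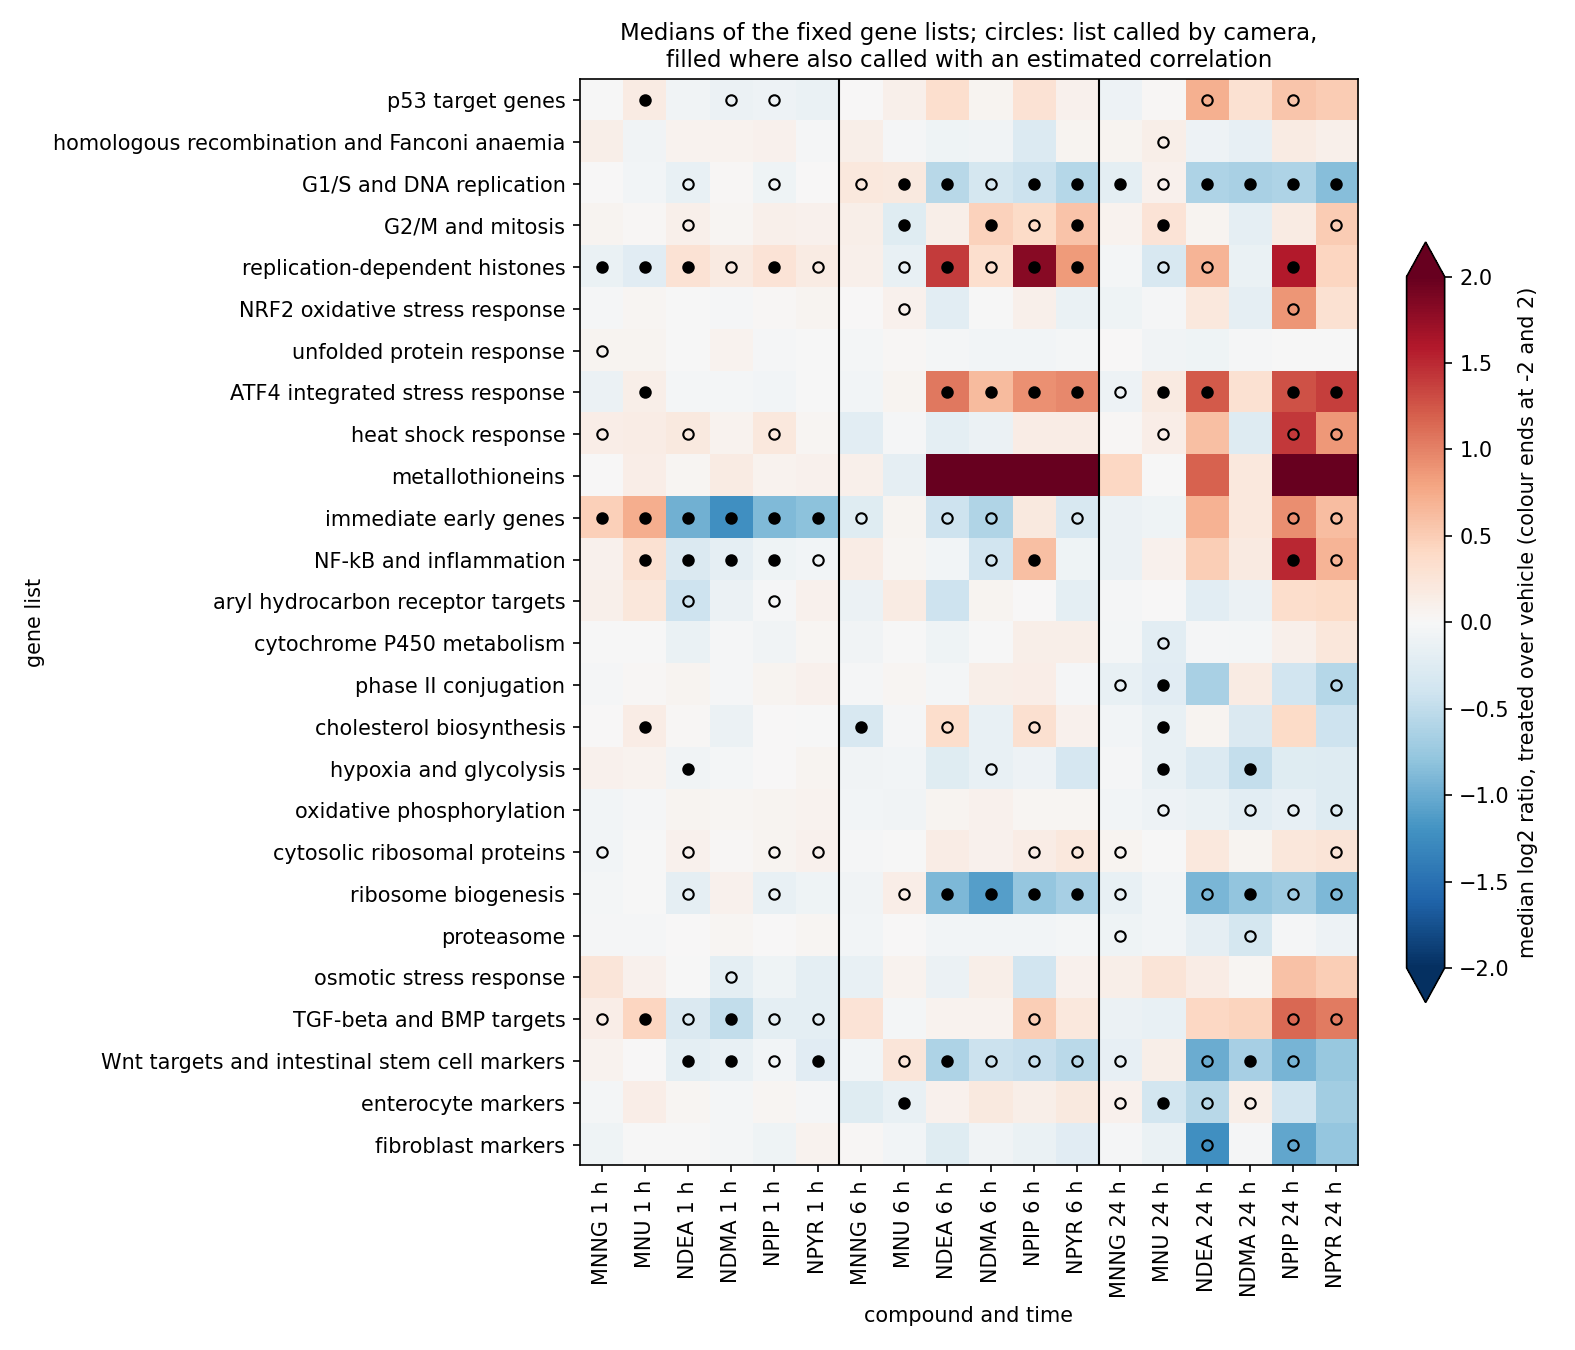
Median log2 ratio, treated over vehicle, of each gene list (lines) in each group (columns, with times parted by black lines), as colour. Circles mark the 152 camera calls, filled for the 64 that also passed with an estimated correlation; the metallothionein list, with medians from 2.50 to 4.84 in the nitrosamines at 6 h, could not be tested by camera.

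At 24 h NDEA, NPIP and NPYR changed 8023, 8091 and 8600 genes and NDMA 3689. With array weights the order turned for 2 of these compounds, at 5578 genes with NDMA against 4002 with NDEA and 4629 with NPIP. ARRDC3 reached 5.64 ± 0.32, 6.11 ± 0.32 and 6.09 ± 0.32 with NDEA, NPIP and NPYR and 2.54 ± 0.32 with NDMA. The chemokine receptor CXCR4 reached 4.88 ± 0.14 (SE, adjusted p = 8.88e-16) with NPYR and 3.54 ± 0.14 (SE, adjusted p = 1.98e-13) with NDEA, and HSPA4L, a heat shock protein, 4.14 ± 0.20 with NDEA. MT1F and SLC30A1, a zinc exporter, rose with NPIP to 5.20 ± 0.15 (SE, adjusted p = 8.07e-15) and 5.17 ± 0.19 (SE, adjusted p = 8.21e-14). NFE2, a haematopoietic transcription factor, fell to -4.18, -3.50 and -3.78 with NDEA, NPIP and NPYR and to -1.85 with NDMA (SE 0.18), and MSMB, a secreted protein, to -3.75 with NDEA. MGMT, which removes alkyl groups from guanine, fell to -0.82, -0.39, -0.91 and -1.43 with NDEA, NDMA, NPIP and NPYR (largest adjusted p = 0.0161, for NDMA, with 0.128 without replicate 1 and 0.178 without replicate 2). CDKN1A, the cell cycle inhibitor p21, rose with NPYR to 0.84 ± 0.079 (SE, adjusted p = 1.5e-08).

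The ATF4 list rose with NDEA, NPIP and NPYR, 20, 20 and 21 of 26 members both over all genes and adjusted over the list alone (largest camera adjusted p = 1.2e-06), with ASNS at 3.55 ± 0.12, 3.01 ± 0.12 and 3.52 ± 0.12. NF-kB genes rose with NPIP, 14 of 21 (15 adjusted over the list alone, camera adjusted p = 0.00069), CXCL3 at 3.69 ± 0.21. Histone genes rose with NPIP, 18 of 24 on both adjustments (adjusted over the list alone, 18; camera adjusted p = 6.01e-08), H1-2, a linker histone, at 3.37 ± 0.10. Heat shock genes rose with NPIP and NPYR, 13 and 13 of 18 (13 and 13 adjusted over the list alone), HSPA1A at 3.52 ± 0.20 and 2.60 ± 0.20. Both heat shock calls were lost with an estimated correlation (adjusted p = 0.189 and 0.309 with an estimated correlation). NRF2 targets rose with NPIP, 13 of 22 with 4 lower (13 and 4 adjusted over the list alone; adjusted p = 0.112 with an estimated correlation), GCLM, of glutathione synthesis, at 2.74 ± 0.18. Of 24 p53 targets 15 rose with NDEA and 14 with NPIP, 4 being lower in each (15 higher in each adjusted over the list alone; adjusted p = 0.138 for both with an estimated correlation, and 0.0524 for NPIP without replicate 2), with TP53I3, a p53-induced oxidoreductase, at 2.09 ± 0.094 for NDEA.

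With NDMA at 24 h, genes of hypoxia and glycolysis fell, 14 of 22 on both adjustments (adjusted over the list alone, 14; camera adjusted p = 1.07e-05), SLC2A1 to -2.10 and ENO1, enolase, to -1.16. Wnt targets and stem cell markers fell with NDMA, 10 of 12 (11 adjusted over the list alone, camera adjusted p = 5.13e-05). It was called lower with NDEA and NPIP at 24 h too, 8 and 8 members (8 and 8 adjusted over the list alone; adjusted p = 0.0688 and 0.176 with an estimated correlation). Proteasome genes fell with NDMA, 15 of 28 (20 adjusted over the list alone; adjusted p = 0.0615 with an estimated correlation). G1/S and replication genes fell with all 4, 24, 22, 22 and 22 of 28 (24, 23, 22 and 22 adjusted over the list alone, camera adjusted p up to 8.87e-06), with MCM4, a replicative helicase subunit, at -2.50 ± 0.15 for NDEA. Enterocyte markers were called lower with NDEA, 10 of 17, and higher with NDMA, 6 (10 and 7 adjusted over the list alone), SI, sucrase-isomaltase, at 1.84 ± 0.26 with NDMA. Both calls were lost with an estimated correlation (adjusted p = 0.0685 and 0.106 with an estimated correlation) and without replicate 2 (0.0676 and 0.0752). Fibroblast markers were lower with NDEA and NPIP, 4 of 5 in each (4 and 5 adjusted over the list alone; adjusted p = 0.114 and 0.126 with an estimated correlation, and 0.0859 and 0.0888 without replicate 2). Caco-2 is a single cell line, so the fibroblast markers do not count fibroblasts, and how near their signals lay to background was not examined. In total 4273 genes rose and 3750 fell with NDEA, 1803 and 1886 with NDMA, 4229 and 3862 with NPIP, and 4355 and 4245 with NPYR. On their replicate 1 arrays NDEA, NPIP and NPYR gave wider ratios (slopes of replicate 2 on replicate 1 of 0.632, 0.656 and 0.8), and without replicate 1 the counts were 4726, 4768 and 6207; those of NDMA were 1701 and 1750 without replicate 1 and without replicate 2. With arrays scaled to one spread, 4053, 4314 and 4720 genes were called for NDEA, NPIP and NPYR and 3320 for NDMA.

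**Figure D3:**
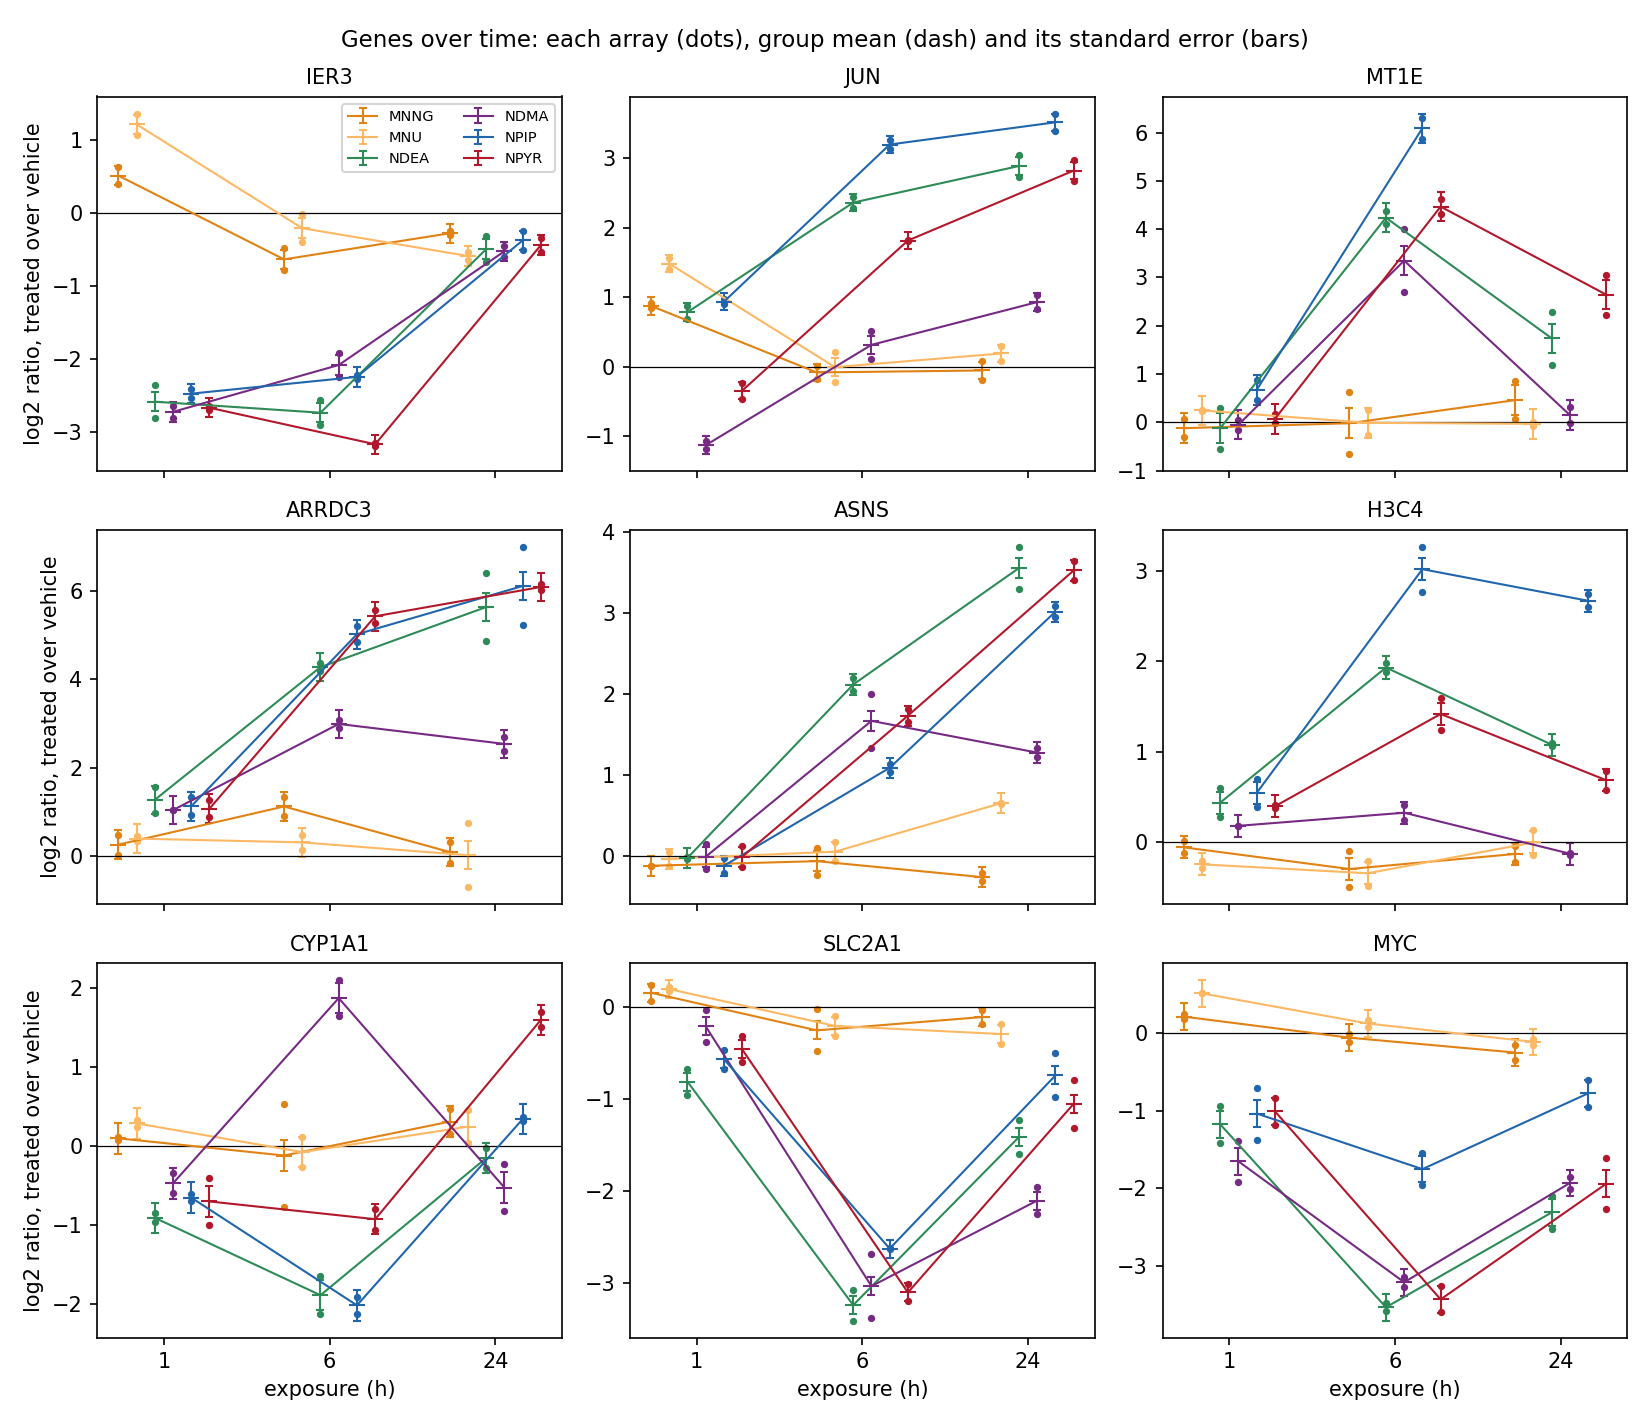
Log2 ratio, treated over vehicle, of 9 genes against exposure time (not to scale), with dots for single arrays, dashes joined by lines for group means and bars for standard errors. IER3 is negative at 1 h with the 4 nitrosamines, and MT1E at 6 h runs from 3.35 with NDMA to 6.09 with NPIP; MT1E has no value for NPIP at 24 h.

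In the main fit the nitrosamides changed few genes at 6 and 24 h, apart from MNNG at 6 h. Array weights gave 738 genes for MNU at 6 h, 1006 for MNU at 24 h and 998 for MNNG at 24 h. With MNU at 6 h, mitotic genes fell and G1/S genes rose as lists, 8 of 30 and 8 of 28 members adjusted over the list alone, with camera adjusted p of 5.19e-11 and 5.8e-06. Over all genes 2 mitotic members fell with MNU at 6 h, KIF20A, a mitotic kinesin, to -0.66 (adjusted p = 0.0124). At 24 h mitotic genes rose with MNU, 2 over all genes and 14 adjusted over the list alone (camera adjusted p = 4.81e-14), KIF2C at 0.55 ± 0.10 (SE, adjusted p = 0.0104). Enterocyte markers fell with MNU at 24 h, 4 of 17 (8 adjusted over the list alone, camera adjusted p = 1.11e-08), MEP1A, a brush border protease, to -0.73 and LCT, lactase, to -0.93. Phase II conjugation genes fell with MNU at 24 h, 2 of 19 (4 adjusted over the list alone, camera adjusted p = 9.13e-07), EPHX2, an epoxide hydrolase, to -0.56. The ATF4 list rose with MNU at 1 and 24 h, 3 and 1 of 26 (5 and 1 adjusted over the list alone, camera adjusted p of 2.8e-05 and 0.00017). It shares ATF3 with the immediate early list. Histone genes were called lower with MNU at 6 and 24 h, 1 and 4 of 24 (2 and 9 adjusted over the list alone; adjusted p = 0.0615 and 0.0595 with an estimated correlation). CA12, a carbonic anhydrase, and GPNMB, a membrane glycoprotein, fell to -1.46 and -1.76. Leaving out 1 array ended the calls of these genes, KIF20A, KIF2C, CA12 and EPHX2 without either replicate. MEP1A and GPNMB lost theirs without replicate 1 (at -0.6194 and -0.9286) and LCT without replicate 2 (at -0.6723). MNU changed 42 genes at 6 h and 99 at 24 h, 34 and 80 of them lower. Without replicate 1 or without replicate 2 these counts were 10 and 11 at 6 h and 15 and 10 at 24 h. With arrays scaled to one spread they were 1151 (468 higher) and 1192 (427 higher).

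With MNNG at 6 h, 526 genes rose and 967 fell, but the replicates differed: without replicate 1 109 genes were called, and without replicate 2 2172. With array weights 19 were called, without the replicate block 719 and with each time fitted alone 663. Cholesterol biosynthesis genes fell, 6 of 20 (9 adjusted over the list alone, camera adjusted p = 0.0021, and 0.073 without replicate 2), INSIG1, a regulator of sterol synthesis, to -0.49. G1/S genes rose, 9 of 28 (10 adjusted over the list alone; adjusted p = 0.0839 with an estimated correlation), CDC6 at 0.61 ± 0.13 (SE, adjusted p = 0.00659). MED18, a Mediator subunit, and H1-5, a linker histone, fell to -3.23 and -1.79. Omission of 1 array ended the calls of CDC6, MED18 and H1-5 (0.4938, -2.52 and -1.431 without replicate 1) and of INSIG1 (-0.2805 without replicate 2). Array weights ended all 4 calls (adjusted p = 0.141 to 0.502). At 24 h 5 genes were called with MNNG and 997 had an unadjusted p under 0.05. CEP128, a centriolar protein, and PRR15L rose to 1.41 ± 0.25 (SE, adjusted p = 0.0365) and 0.52 ± 0.091 (SE, adjusted p = 0.0365), and LAMP3, UBD and IGFL2 fell to -1.13, -0.69 and -0.65. Without either replicate the calls of PRR15L, LAMP3, UBD and IGFL2 ended, and without replicate 2 that of CEP128 ended, at 0.872. CEP128 moved with the choice of probes, to 2.464 with the most variable probe and 0.3535 (adjusted p = 0.832) with the features that have a value on every array. All 5 calls ended with the most variable probe (adjusted p = 0.051 to 0.0667), without the replicate block (0.0751 to 0.546) and with each time fitted alone (0.23 to 0.732). The G1/S list fell with MNNG at 24 h by camera (median -0.19, 2 of 28 members adjusted over the list alone, adjusted p = 9.66e-07). Without replicate 2 the 24 h count was 2, and with arrays scaled to one spread it was 793.

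**Figure D4:**
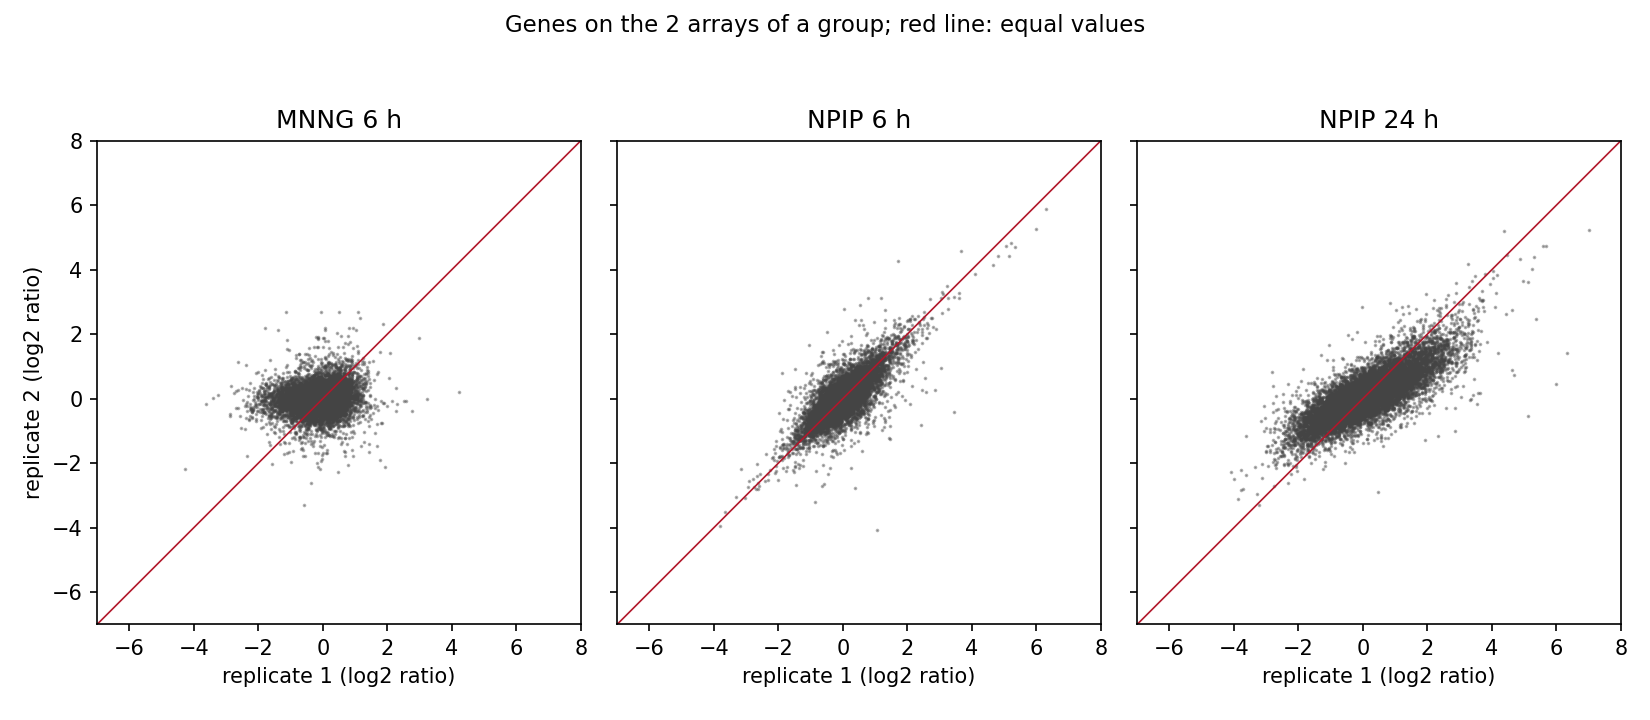
Log2 ratio of each gene on the replicate 1 array (horizontal) and the replicate 2 array (vertical) of 3 groups, with a red line where the 2 are equal. The slope of replicate 2 on replicate 1, with the dye term removed, is 0.315 for MNNG at 6 h, 1.02 for NPIP at 6 h and 0.656 for NPIP at 24 h.

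The second question, which the series title poses, was how responses differed between times within a compound. IER3, low at 1 h with the nitrosamines, was higher at 24 h than at 1 h, by 2.20 ± 0.19 (SE, adjusted p = 3.19e-07) for NDMA and 2.23 ± 0.19 (SE, adjusted p = 1.45e-08) for NPYR, and stood at -0.53 ± 0.13 and -0.44 ± 0.13 at 24 h. These 24 h calls ended without NDMA replicate 1 (-0.4588) and NPYR replicate 2 (-0.3318). Both ended with arrays scaled to one spread, at -0.4593 and -0.2215 (adjusted p = 0.162 and 0.511), and that of NPYR with array weights (adjusted p = 0.111). GDF15 turned from low to high, the same difference being 4.59 ± 0.21 (SE, adjusted p = 8.62e-12) with NPIP. JUN, high at 1 h with MNU, was lower at 6 h, by -1.49 ± 0.18 (SE, adjusted p = 0.00026). SLC2A1 was higher at 24 h than at 6 h with NDEA, by 1.83 ± 0.14 (SE, adjusted p = 1.64e-08), and ASNS went on rising, by 1.44 ± 0.18 (SE, adjusted p = 5.47e-06). With arrays scaled to one spread this ASNS difference was only 0.2646 and was not called (adjusted p = 0.612). With NDMA the 24 h minus 6 h difference of ASNS did not pass the test, at -0.39 ± 0.18 (SE, adjusted p = 0.189). The F test of equal times called 278 genes for MNNG, 84 for MNU, 6410 for NDEA, 3189 for NDMA, 6743 for NPIP and 7673 for NPYR. From 6 to 24 h 1345 genes differed with NDMA and 5444 with NPIP. Leaving out 1 array gave 91 and 1145 genes for MNNG (6 h replicates 1 and 2) and 85 and 58 (24 h replicates 1 and 2). For MNU it gave 16 and 54 (1 h replicates 1 and 2), 51 (6 h replicate 2) and 42 and 35 (24 h replicates 1 and 2). The NDMA count was 2050 without its 1 h replicate 2, and that of NPIP 4281 without its 24 h replicate 1. With arrays scaled to one spread, 1084 genes differed between times for MNNG, 1372 for MNU, 2566 for NDEA, 3397 for NPIP and 3906 for NPYR.

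The third question was how the nitrosamides, taken as a class, differed from the nitrosamines, with the doses differing throughout. The p values and intervals here measure the spread between arrays of the same compound and time, not the spread between compounds of a class. They hold for these 6 compounds at these doses and not for the classes at large. At 1 h 22 of 25 immediate early genes were higher with the nitrosamides (23 adjusted over the list alone), IER3 by 3.48 (95% interval 3.23 to 3.71, adjusted p = 5.17e-14) and EDN1 by 3.75 (95% interval 3.36 to 4.13, adjusted p = 2.23e-11). At 6 h all 8 measured members of the metallothionein list (8 adjusted over the list alone) and 23 of 24 histone genes (23 adjusted over the list alone) were lower with the nitrosamides, MT2A by -4.67 (95% interval -5.11 to -4.23, adjusted p = 6.69e-12). The ATF4 list was lower with the nitrosamides at 6 and 24 h, 21 and 20 of 26 members (21 and 20 adjusted over the list alone). At 24 h ARRDC3 was lower with the nitrosamides, by -5.04 (95% interval -5.62 to -4.45, adjusted p = 2.58e-11), and NFE2 higher, by 3.50 (95% interval 3.17 to 3.83, adjusted p = 1.29e-12). The classes differed in 375 genes at 1 h, 5358 at 6 h and 7952 at 24 h. At 1 h 292 of these were higher with the nitrosamides, at 6 h 2343 and at 24 h 3793. Without the MNU replicate 2 array the 1 h count was 228, and with arrays scaled to one spread it was 1681 (928 higher); the 24 h count was then 5025.

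The last question was how related compounds differed. NPYR, a nitrosamine whose nitrogen sits in a ring, and NDMA, whose nitrogen carries 2 methyl groups, were both given at 100 mM. At 24 h CDYL2, a chromodomain protein, was higher with NPYR by 5.12 (95% interval 4.07 to 6.16, adjusted p = 3.05e-07), and ATF4 genes (20 of 26), heat shock genes (16 of 18) and mitotic genes (22 of 30) were higher with NPYR (20, 16 and 23 adjusted over the list alone). Enterocyte markers were lower with NPYR at 24 h, 10 of 17 (11 adjusted over the list alone). At 6 h CYP1A1 was lower with NPYR than with NDMA, by -2.80 (95% interval -3.37 to -2.23, adjusted p = 2.22e-06), and ARRDC3 higher, by 2.44 (95% interval 1.48 to 3.39, adjusted p = 0.00232). At 1 h FOS differed by 1.52 (95% interval 0.95 to 2.08, adjusted p = 0.0466) and MIR17HG by -1.78 (95% interval -2.32 to -1.24, adjusted p = 0.00536). NPYR and NDMA differed in 5 genes at 1 h, 1026 at 6 h and 5513 at 24 h. The difference had a 95% interval within 1 on the log2 scale, either way, for 74.9%, 65.7% and 43.5% of genes at 1, 6 and 24 h. Omission of 1 array gave 0 genes by limma at 1 h for NPYR replicate 2 (414 with an unadjusted p under 0.05) and 8 for replicate 1 of either compound. At 6 h it gave 276 for NPYR replicate 2, 291 for NDMA replicate 2 and 449 for NDMA replicate 1, and at 24 h 3275 for NPYR replicate 1 and 3524 for NDMA replicate 1. Scaling arrays to one spread gave 160, 336 and 1217. The call of ARRDC3 at 6 h ended without NPYR replicate 2 (adjusted p = 0.0586), that of FOS without NPYR replicate 2 or either NDMA array (0.158 to 0.657), and that of MIR17HG without NDMA replicate 2 or either NPYR array (0.0794 to 0.142). With scaled arrays the calls ended of ARRDC3 (difference of 1.506, adjusted p = 0.131), MIR17HG (-2.126, 0.0521) and CDYL2 (2.106, 0.0502).

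At 6 h the dialkyl nitrosamines NDEA (ethyl groups, 50 mM) and NDMA (methyl groups, 100 mM) differed most in CYP1A1, by -3.76 (95% interval -4.33 to -3.20, adjusted p = 7.37e-08), and in CYP1B1, another target of the same receptor, by -3.22 (95% interval -3.94 to -2.50, adjusted p = 1.47e-05). Histone genes at 6 h were higher with NDEA, 17 of 24, and at 24 h so were ATF4 genes, 18 of 26 (20 and 21 adjusted over the list alone). JUN was higher with NDEA by 1.91, 2.05 and 1.96 at 1, 6 and 24 h. NDEA and NDMA differed in 14, 594 and 3972 genes at 1, 6 and 24 h, and the interval lay within 1 for 73.8%, 70.1% and 50.2% of genes. Leaving out 1 array gave 9 genes at 1 h for NDMA replicate 2. At 6 h it gave 215 and 233 for NDEA replicates 1 and 2 and 237 and 228 for those of NDMA, and at 24 h 1447 for NDEA replicate 1 and 1810 for NDMA replicate 1. Scaling arrays to one spread gave 469 (303 higher), 139 and 592, and ended the call of JUN at 24 h, with a difference of 0.7354 (adjusted p = 0.202).

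The cyclic nitrosamines NPIP (6-membered ring, 40 mM) and NPYR (5-membered ring, 100 mM) differed at 24 h in MT1F, higher with NPIP by 5.50 (95% interval 5.06 to 5.94, adjusted p = 3.54e-12), and SLC30A1, by 3.77 (95% interval 3.21 to 4.33, adjusted p = 2.22e-08). At 6 h 7 of 8 members of the metallothionein list, 15 of 24 histone genes and 11 of 21 NF-kB genes were higher with NPIP (8, 16 and 12 adjusted over the list alone). At 1 h JUN and SNHG8 were higher with NPIP, by 1.28 (95% interval 0.91 to 1.65, adjusted p = 0.0078) and 1.01 (95% interval 0.67 to 1.35, adjusted p = 0.0359). NPIP and NPYR differed in 2, 787 and 1638 genes at 1, 6 and 24 h, and the interval lay within 1 for 79%, 68% and 64% of genes. Leaving out NPIP replicate 2 or NPYR replicate 1 gave 0 genes by limma at 1 h (278 and 394 with an unadjusted p under 0.05). The call of JUN ended without NPIP replicate 2 (difference of 1.232) or NPYR replicate 1 (1.15), and that of SNHG8 without any of the 4 arrays (0.8732 to 1.149). Omission of 1 array gave 247 genes at 6 h for NPYR replicate 2, 291 and 415 for NPIP replicates 2 and 1, and 943 at 24 h for NPYR replicate 1, and scaling arrays to one spread gave 14 (7 higher), 270 and 19 (16 higher). The nitrosamides MNU (1 mM) and MNNG (1 µM) differed at 24 h in CA12, lower with MNU by -1.93 (95% interval -2.58 to -1.28, adjusted p = 0.0125), and ASNS, higher by 0.91 (95% interval 0.54 to 1.28, adjusted p = 0.0354). MNU and MNNG differed in 0 genes at 1 h by limma (463 with an unadjusted p under 0.05), 54 at 6 h and 29 at 24 h. The interval lay within 1 for 77.8%, 70% and 76.9% of genes. Leaving out MNNG replicate 1 gave 5, 16 and 12 genes at 1, 6 and 24 h, MNNG replicate 2 gave 2, 1119 and 3, MNU replicate 1 gave 1, 6 and 4, and MNU replicate 2 gave 1, 6 and 3. Scaling arrays to one spread gave 56 (35 higher), 227 and 584 (192 higher). Leaving out any of the 4 arrays of 24 h ended the calls of CA12 and ASNS (adjusted p = 0.0824 to 0.284).

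Profiles of compounds were compared by correlation across genes, which are not independent replicates. At 1 h MNNG and MNU correlated at 0.275 and the nitrosamines at 0.283 (NDMA and NPIP) to 0.67 (NDEA and NPIP) with each other. MNNG and MNU correlated at 0.287 at 6 h and 0.161 at 24 h. At 6 h NDEA and NPYR correlated at 0.846, with 2008 genes higher in both where independent draws give 600.9, and NDMA and NPIP at 0.649. At 24 h NDEA, NPIP and NPYR correlated at 0.881 to 0.896 with each other and NDMA at 0.52 to 0.646 with these 3. The labels do not say whether vehicle RNA was shared between compounds; if it was, part of these overlaps and correlations comes from it. After the dye term, the differences between replicates of NDEA, NPIP and NPYR at 24 h correlated at 0.492 to 0.686 with each other, with covariances of 0.0348 to 0.0578 against 0.689 to 0.789 for the responses. At 1 h these differences correlated at 0.322 for NDEA and NPIP, 0.252 for NPIP and NPYR and 0.267 for MNNG and MNU, with covariances of 0.00935, 0.0073 and 0.00769 against 0.0474, 0.0413 and 0.0111 for the responses.

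Of the 34 gene lists, 33 were tested in the 18 groups, and 152 of 594 tests passed, 68 higher and 84 lower; 64 of the 152 passed with an estimated correlation. In each of the 152 the median, the mean and the test had the same sign. Lists of direct reversal and base excision repair, nucleotide excision repair, mismatch repair, interferon response, apoptosis regulators, fatty acid oxidation, leukocyte markers and goblet, Paneth and enteroendocrine markers passed in no group. The cholesterol biosynthesis list was called higher with MNU at 1 h (1 of 20, 1 adjusted over the list alone, camera adjusted p = 0.000463). Oxidative phosphorylation genes were called lower with NDMA at 24 h (18 of 44, 22 adjusted over the list alone; adjusted p = 0.155 with an estimated correlation), and cytosolic ribosomal proteins higher with NPYR (29 of 48, 29 adjusted over the list alone; adjusted p = 0.247 with an estimated correlation and 0.0819 without replicate 1). The unfolded protein response was called higher with MNNG at 1 h (adjusted p = 0.175 with an estimated correlation), homologous recombination and Fanconi anaemia genes higher with MNU at 24 h (0.156) and cytochrome P450 metabolism lower with MNU at 24 h (0.0535), 2 members of each of the last 2 passing adjusted over the list alone. Aryl hydrocarbon receptor targets were called lower with NDEA and NPIP at 1 h (1 of 7 each, 2 each adjusted over the list alone; adjusted p = 0.198 and 0.156 with an estimated correlation), and osmotic stress genes with NDMA at 1 h (1 of 6, 1 adjusted over the list alone; 0.172). These last 6 calls were also lost without 1 of the replicates, replicate 1 for recombination (0.0745), P450 (0.054), NPIP (0.116) and the unfolded protein response (0.19), and replicate 2 for NDEA (0.146), NDMA (0.458) and the unfolded protein response (0.124). CYP2E1, a cytochrome P450 that activates NDMA, had too few values to be tested.

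Further list calls stand beside those given above. Ribosome biogenesis genes fell with NDMA at 24 h, 17 of 22 (18 adjusted over the list alone, camera adjusted p = 8.16e-10), and hypoxia and glycolysis genes with NDEA at 1 h, 3 of 23 (4 adjusted over the list alone, camera adjusted p = 0.00487, and 0.0517 without replicate 1). The calls in the rest of this paragraph were lost with an estimated correlation. At 6 h immediate early genes were called lower with NDEA, NDMA, NPYR and MNNG, 12, 14, 12 and 8 of 25 (12, 15, 12 and 9 adjusted over the list alone; adjusted p = 0.232, 0.0846, 0.399 and 0.335 with an estimated correlation, and 0.319 for MNNG without replicate 2), and at 24 h higher with NPIP and NPYR, 15 and 15 of 25 with 5 lower in each (15 and 15 adjusted over the list alone; adjusted p = 0.294 and 0.346 with an estimated correlation). Ribosome biogenesis genes were called lower at 24 h with NDEA, NPIP and NPYR too, 18, 13 and 15 of 22 (18, 16 and 15 adjusted over the list alone; adjusted p = 0.105, 0.294 and 0.181 with an estimated correlation, and 0.0575 for NPIP without replicate 2). With NPYR at 24 h NF-kB genes and mitotic genes were called higher, 13 of 21 (14 adjusted over the list alone; adjusted p = 0.0846 with an estimated correlation) and 21 of 30 (22 adjusted over the list alone; adjusted p = 0.244 with an estimated correlation), and phase II genes lower, 14 of 19 (14 adjusted over the list alone; adjusted p = 0.145 with an estimated correlation, and 0.072 without replicate 2). Histone genes were called higher with NDEA at 24 h, 15 of 24 (16 adjusted over the list alone; adjusted p = 0.221 with an estimated correlation, and 0.0593 without replicate 2), and TGF-beta targets with NPIP at 6 h and with NPIP and NPYR at 24 h, 7, 8 and 8 of 11 (7, 9 and 8 adjusted over the list alone; adjusted p = 0.337, 0.221 and 0.21 with an estimated correlation, and 0.0924 for NPIP at 6 h without replicate 2). Cholesterol biosynthesis genes were called higher with NDEA and NPIP at 6 h, 7 and 8 of 20 (7 and 11 adjusted over the list alone; adjusted p = 0.0963 and 0.052 with an estimated correlation, and 0.0528 for NDEA without replicate 2), and hypoxia genes lower with NDMA at 6 h, 6 of 23 (6 adjusted over the list alone; adjusted p = 0.052 with an estimated correlation). Oxidative phosphorylation genes were called lower with NPIP and NPYR at 24 h, 20 and 24 of 44 with 10 and 8 higher (20 and 24 adjusted over the list alone; adjusted p = 0.448 and 0.426 with an estimated correlation, and 0.27 and 0.26 without replicate 2), and ribosomal proteins higher with NPIP and NPYR at 6 h, 10 and 15 of 48 (9 and 14 adjusted over the list alone; adjusted p = 0.269 and 0.215 with an estimated correlation, and 0.0743 for NPIP without replicate 2). The calls not named in the text had at most 2 members past the threshold over all genes, and the figure of the lists marks them.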

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

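The test of dye orientation for the smaller replicate 2 responses at 24 h, the test of S phase for the histone genes and the splits of the compounds were chosen only after their results were seen. The other tests of an explanation in this part were written after the pattern was seen but before their own results. The limma comparisons of compounds and times were planned.

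The compounds and times differed in the genes they changed, by limma tests of the difference itself. Nitrosamides and nitrosamines differed in 375 genes at 1 h, 5358 at 6 h and 7952 at 24 h. MNU and MNNG differed in 54 genes at 6 h and 29 at 24 h. NDEA and NDMA differed in 14, 594 and 3972 genes at 1, 6 and 24 h, NPIP and NPYR in 2, 787 and 1638, and NPYR and NDMA in 5, 1026 and 5513. Between times, 278 genes differed for MNNG, 84 for MNU, 6410 for NDEA, 3189 for NDMA, 6743 for NPIP and 7673 for NPYR. The class belongs to the compound, and the 15 splits of the 6 compounds into 2 and 4 are too few for a share under 0.05: 1 of the 15, the real one, gave as many genes at each of the 3 times. The highest count of another split was 120 at 1 h, 3298 at 6 h and 7281 at 24 h.

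Features without a gene name, which enter no comparison above, carried signal too. Of 6312 with enough values, 5025 were called in at least 1 of the 18 comparisons, most often with NPYR at 24 h (3290), NPIP at 24 h (3198) and NDEA at 24 h (3192).

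MNNG at 6 h changed 1493 genes, with a response that differed in size between the replicates. Of the called genes, 88 were still called the same way without replicate 1 and 1131 without replicate 2, so most of the count may rest on the replicate 1 array. RNA of a nitrosamine group of 6 or 24 h on that array is not borne out. Over the genes with a value on every array, with the dye term removed, its profile correlated at 0.249 at most with the mean of another group, MNNG at 1 h. With its own replicate it correlated at 0.336. RNA of a nitrosamide or 1 h group cannot be told by this test, since replicates of those groups correlate at only 0.0985 to 0.399. Why that array differs stays open, and no biological explanation was tested.

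At 24 h the responses to NDEA, NPIP and NPYR were smaller on the replicate 2 arrays, with slopes of 0.632, 0.656 and 0.8. Dye orientation is not borne out as the cause: in 5 other strong nitrosamine groups with the same orientations the median slope was 1.02. Replicate 2 cultures at an earlier stage of the response cannot be told apart from a plain difference in size, since the partial correlations with the change from 6 to 24 h were 0.154 to 0.179, between the bounds set for either answer. A difference in exposure between the replicate cultures was not tested and stays open.

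Replication-dependent histone genes rose at 6 h with NDEA, NPIP and NPYR, the highest group median being 1.82 with NPIP. Dye bias is not borne out, since the medians of the histone genes were 0.673 or more on each of the 6 arrays of both orientations. Whether more cells were in S phase was not decided. The medians of the G1/S and replication genes were -0.487 or less on each of these arrays, so these genes show no added entry into S phase. That fall was known when the test was chosen, and the list does not measure how long cells stay in S phase. Transcripts of these histone genes normally lack a poly(A) tail, and variant histone genes with a tail had medians of at most 0.214 in the 3 compounds where the replication histones had at least 0.854. As a hypothesis, the change may be special to histone transcripts without a tail; tails were not measured.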

How the results depend on the processing

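The fits of each time alone, those without the MNNG 6 h arrays or the 3 replicate 1 arrays of 24 h, the count of genes with the same direction on both arrays and the lists with each array left out were chosen only after the data were seen; the other alternatives were planned. The larger nitrosamine responses at 6 and 24 h stood under most alternatives, while the nitrosamide counts and all counts at 1 h moved with several of them. No alternative turned the direction of any of the 142 values of named genes that passed the test; of 1774 recomputed values 1642 stayed past the threshold and 132 did not, 65 of these on leaving out an array. That no direction turned is no test of stability. Many of these genes were named partly for the same direction on both arrays, so leaving out an array could hardly turn them. Several alternatives also leave the estimate as it was, such as 0.7802 for KLF6 with MNNG at 1 h without the replicate block. Deposited values without centring, genes with a value on every array, the robust prior and the count of genes with the same direction on both arrays kept each count within 1.5 times. The array medians were close to 0 as deposited, the furthest at -0.037, so leaving out centring could change little. Genes with the same direction on both arrays are a part of the called genes. Neither setting shows that the median gene was unchanged, which centring assumes. Precision rests on 2 arrays per group, and signal over background was not used here.

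Without the replicate block (here the dye term), these counts of called genes moved. At 1 h they were 1 for MNNG, 29 for MNU, 177 for NDEA, 133 for NPIP and 114 for NPYR. At 6 h they were 719 for MNNG and 14 for MNU. At 24 h they were 0 (671 with an unadjusted p under 0.05) for MNNG and 32 for MNU. The classes differed in these numbers of genes: 235 at 1 h. MNU minus MNNG gave 11 at 6 h and 7 at 24 h. NDEA minus NDMA gave 3 at 1 h and 293 at 6 h. NPIP minus NPYR gave 1 at 1 h, 437 at 6 h and 988 at 24 h. NPYR minus NDMA gave 0 (534 with an unadjusted p under 0.05) at 1 h and 491 at 6 h. Between times they were 60 for MNNG and 27 for MNU. Fewer genes passed in each of these; the cause was not tested. Gene lists called numbered 145.

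With arrays scaled to one spread, which widens the ratios of arrays with small responses and narrows those of arrays with large ones, these counts moved. At 1 h they were 425 for MNNG, 643 for MNU, 1425 for NDEA, 795 for NDMA, 1179 for NPIP and 1179 for NPYR. At 6 h it was 1151 for MNU. At 24 h they were 793 for MNNG, 1192 for MNU, 4053 for NDEA, 4314 for NPIP and 4720 for NPYR. The classes differed in these numbers of genes: 1681 at 1 h and 5025 at 24 h. MNU minus MNNG gave 56 at 1 h, 227 at 6 h and 584 at 24 h. NDEA minus NDMA gave 469 at 1 h, 139 at 6 h and 592 at 24 h. NPIP minus NPYR gave 14 at 1 h, 270 at 6 h and 19 at 24 h. NPYR minus NDMA gave 160 at 1 h, 336 at 6 h and 1217 at 24 h. Between times they were 1084 for MNNG, 1372 for MNU, 2566 for NDEA, 3397 for NPIP and 3906 for NPYR.

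Array weights were low for NDEA (0.223) and NPIP (0.255) at 24 h and MNNG at 6 h (0.357), where counts fell. They were high for MNNG (2.17) and MNU (1.75) at 24 h, where counts rose. The main fit gave all groups one spread per gene. Its standard errors may thus be too small for groups of low weight and too large for those of high weight. What made the weights unequal was not tested. With array weights, these counts moved. At 1 h they were 17 for MNNG, 74 for MNU, 1322 for NDEA, 347 for NDMA, 352 for NPIP and 951 for NPYR. At 6 h they were 19 for MNNG, 738 for MNU and 6649 for NPIP. At 24 h they were 998 for MNNG, 1006 for MNU, 4002 for NDEA, 5578 for NDMA and 4629 for NPIP. The classes differed in these numbers of genes: 771 at 1 h. MNU minus MNNG gave 0 (1059 with an unadjusted p under 0.05) at 6 h and 562 at 24 h. NDEA minus NDMA gave 77 at 1 h, 1260 at 6 h and 1373 at 24 h. NPIP minus NPYR gave 9 at 1 h, 1895 at 6 h and 150 at 24 h. NPYR minus NDMA gave 36 at 1 h and 2101 at 6 h. Between times they were 482 for MNU and 5360 for NDMA. At 24 h NDMA then had more called genes than NDEA and NPIP.

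Without the 3 replicate 1 arrays of NDEA, NPIP and NPYR at 24 h, these counts moved, and the cause was not tested. At 1 h they were 9 for MNNG, 98 for MNU, 653 for NDEA, 304 for NDMA, 497 for NPIP and 480 for NPYR. At 6 h they were 2629 for MNNG and 235 for MNU. At 24 h they were 12 for MNNG and 339 for MNU. The classes differed in these numbers of genes: 686 at 1 h. MNU minus MNNG gave 204 at 6 h and 110 at 24 h. NDEA minus NDMA gave 25 at 1 h, 1244 at 6 h and 2224 at 24 h. NPIP minus NPYR gave 1522 at 6 h. NPYR minus NDMA gave 3 at 1 h and 2104 at 6 h. Between times they were 772 for MNNG, 152 for MNU and 4795 for NDMA.

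With each time fitted alone, on 12 arrays and so fewer degrees of freedom, these counts moved. At 1 h they were 0 (1451 with an unadjusted p under 0.05) for MNNG, 31 for MNU and 135 for NPYR. At 6 h they were 663 for MNNG and 0 (1565 with an unadjusted p under 0.05) for MNU. At 24 h they were 0 (730 with an unadjusted p under 0.05) for MNNG, 1 for MNU and 2305 for NDMA. MNU minus MNNG gave 0 (1812 with an unadjusted p under 0.05) at 6 h and 1 at 24 h. NDEA minus NDMA gave 4 at 1 h, 281 at 6 h and 1826 at 24 h. NPIP minus NPYR gave 0 (767 with an unadjusted p under 0.05) at 1 h, 472 at 6 h and 529 at 24 h. NPYR minus NDMA gave 0 (1432 with an unadjusted p under 0.05) at 1 h.

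With the most variable probe of a gene, these counts moved, and the cause was not tested. At 24 h it was 0 (926 with an unadjusted p under 0.05) for MNNG. MNU minus MNNG gave 30 at 6 h and 6 at 24 h. Between times they were 181 for MNNG. Without both MNNG 6 h arrays, MNU at 6 h had 97 called genes. With an estimated correlation 64 gene lists were called, against 152; the cause was not tested.

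When 1 array was left out, the lone array of its group was assumed to vary like those of the other groups, and the counts below run from the lowest to the highest. At 1 h they were 5 to 17 for MNNG, 11 to 18 for MNU, 88 to 120 for NDEA, 90 to 119 for NDMA, 65 to 77 for NPIP and 65 to 70 for NPYR. At 6 h they were 109 to 2172 for MNNG, 10 to 11 for MNU, 2830 to 3436 for NDEA, 2234 to 2241 for NDMA, 2117 to 2223 for NPIP and 2895 to 4047 for NPYR. At 24 h they were 2 to 5 for MNNG, 10 to 15 for MNU, 4726 to 7800 for NDEA, 1701 to 1750 for NDMA, 4768 to 7837 for NPIP and 6207 to 7757 for NPYR. For the classes they were 228 to 334 at 1 h, 4330 to 5168 at 6 h and 6946 to 8284 at 24 h. For MNU minus MNNG they were 1 to 5 at 1 h, 6 to 1119 at 6 h and 3 to 12 at 24 h. For NDEA minus NDMA they were 9 to 14 at 1 h, 215 to 237 at 6 h and 1447 to 5228 at 24 h. For NPIP minus NPYR they were 0 to 3 at 1 h, 247 to 569 at 6 h and 943 to 1409 at 24 h. For NPYR minus NDMA they were 0 to 8 at 1 h, 276 to 800 at 6 h and 3275 to 5422 at 24 h. Between times they were 58 to 1145 for MNNG, 16 to 59 for MNU, 4381 to 7191 for NDEA, 2050 to 2482 for NDMA, 4281 to 7259 for NPIP and 6005 to 7550 for NPYR. Gene lists called numbered 143 to 156; of the 152 calls 99 were kept without either replicate of their group, 19 were lost without replicate 1 and 37 without replicate 2, and no direction turned.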

Other observations

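The zinc finger family was chosen only after ZNF genes were seen among the risers; its test at 1 h with the 4 nitrosamines was written before the medians at 1 h were seen.

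Genes with a ZNF symbol, mostly zinc finger transcription factors, were noticed among the risers. At 6 h, of 379 measured, 164 rose and 37 fell with NDEA, 144 rose and 32 fell with NPIP, and 115 rose and 33 fell with NDMA; of 378 with NPYR, 166 rose and 45 fell. With MNNG at 6 h 22 rose and 15 fell, and with MNU at 6 and at 24 h 0 rose and 0 fell. Few other genes rose with MNU either, 0.0621% at 6 h and 0.147% at 24 h, and the ZNF medians were 0.0881 and 0.135. These counts describe a family picked from the risers and do not test whether it moved apart from other genes.

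Immediate early transcripts, which fell at 1 h with the nitrosamines, are short-lived, and a general loss of short-lived transcripts was tested as a hypothesis on ZNF genes, whose transcripts are mostly short-lived too. At 1 h the ZNF medians were 0.175 with NDEA, 0.0132 with NDMA, 0.138 with NPIP and -0.018 with NPYR. As a set they met neither answer set beforehand, and the family was picked after its genes were seen among the risers. The hypothesis stays open for all 4 compounds.

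The term for dye orientation passed the threshold in 4503 of 13283 genes. In this design it is also the replicate number, and no value here separates dye from replicate.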
